A study of Mus musculus with 21 samples.

How the data were processed

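RNA sequencing measured gene expression in mouse hindlimb muscle, in 21 libraries that form 4 groups of a design with 2 factors, genotype and streptozotocin (STZ). Per the labels, RNA came from powdered quadriceps and gastrocnemius combined and was extracted with Trizol. Libraries were made with a kit that keeps the strand of the transcript, with 48 indexed libraries pooled for sequencing on an Illumina HiSeq instrument.

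The deposited table holds read counts per Ensembl mouse gene, which the authors left without normalization. The submitters' processing notes name the aligner STAR, the counting program featureCounts and the genome build GRCm38.p4. Their versions, the gene annotation, the strand setting and the handling of reads that map to several places are not given in the sources used here. Reads that cannot be placed uniquely can therefore be lost or shared between near-identical genes, and a gene cannot be told apart from an antisense partner unless the count used the strand. The table has 46071 genes, of which 45143 identifiers matched a symbol of the GENCODE mouse release 21 annotation. Identifiers without a symbol held 0.0533% of the counts. Coordinates were taken from that annotation, on GRCm38.

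Each library was assigned to its group from the genotype and drug in its labels. The title numbers 1 to 21 name the libraries and are unique, so no number pairs libraries between groups. The labels do not say whether each library came from a separate animal, so the p-values measure the spread between libraries. No pair of libraries matched within sampling noise: chi-square per degree of freedom over genes with at least 10 counts in a pair was at least 8.68 in 46 pairs of the same group and at least 10.2 in 164 other pairs. The titles' library codes form 6 runs of consecutive codes. The labels do not call these runs batches. After subtraction of the group means, libraries of the same run had a mean correlation of 0.157 in 27 pairs, against -0.0774 between runs, with a one-sided permutation p of 0.001, the smallest that 1000 permutations can give. Every comparison was therefore also fitted with the run as a block.

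Total counts per library ranged from 2951290 to 7687823, with a median of 5665819, and 16113 to 19386 genes had at least 1 count. The 10 most abundant genes took 13.5 to 26.9% of the counts, and mitochondrially encoded genes took 2.7 to 8.46%. TMM factors, which adjust library sizes for composition, ranged from 0.862 to 1.35.

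Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered by filterByExpr with the 4 groups, which kept 12658, and libraries were scaled by TMM. A robust quasi-likelihood model of the 4 group means was fitted to all 21 libraries, so that the groups share 1 estimate of the spread. The biological coefficient of variation was 0.325. The 5 contrasts were the STZ effect in floxed controls, the knockout effect without STZ, the knockout effect under STZ, the STZ effect in knockouts, and the difference between both STZ effects (the interaction). Tests were two-sided, and Benjamini-Hochberg adjustment was applied within each contrast at a threshold of 0.05. Values per library are given as CPM, counts scaled to the TMM-adjusted library size, with means ± SD over libraries. Log2 fold changes are given with the standard error of the coefficient.

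Gene lists were tested with camera in limma 3.58.1, which compares the genes of a list with all other genes, using a preset correlation between genes of 0.01 and adjustment over 40 lists and 5 contrasts. Of 43 lists fixed, the targeted genes and the sex-linked genes were reported per gene, and lymphocyte markers had only 4 measured genes, under the minimum of 5. Camera was repeated with the correlation estimated from the data, and fry was run as a test of each list by itself. Counts of list members that passed are given after adjustment over all genes, and also adjusted over the list alone. Some genes stand in more than 1 list. Mean list levels per library are means of log2 CPM (prior count 2) after subtraction of each gene's mean over all libraries. A slope of the STZ effect in knockouts on the STZ effect in floxed controls was computed over 12648 tested genes, those with finite standard errors under 5 in both comparisons, as the covariance of the fold changes divided by the variance of the floxed-control effect less its mean squared standard error. It was set against permutations of the genotype labels within STZ and within untreated libraries, 100 labellings with the real one included.

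The design, the contrasts, the lists and the rule for named genes were chosen before the data were examined. Named genes were Foxo1, Foxo3 and Foxo4; 13 core genes of muscle wasting and glucose use in every contrast; in each contrast, the 6 genes with the highest and the 6 with the lowest log2 fold change among those past the threshold with a mean log2 CPM of at least 2, leaving out predicted gene models and sex-linked genes; and up to 4 members of each list with the smallest p among those past the threshold. Genes met under 1 contrast could be given in the others, as could genes with a library apart from its group. Genes named outside this rule are marked as such. Not every core gene is printed for every contrast.

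Alternatives fixed beforehand were DESeq2 1.42.0, median-ratio (RLE) factors, no low-count filter, a fit of only the groups compared, the run as a block, limma voom with library quality weights, and leaving out each library in turn. Alternatives added after the data were seen left out libraries 17 and 18, libraries 4, 15, 16 and 20, or libraries 4, 6, 15 and 20, used the mean level of macrophage markers as a covariate, or combined the run block with leaving out libraries 17 and 18. A sex covariate had been planned and could not be fitted, because Xist had 0 to 2 counts in each library.

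The procedure was tested on simulated counts for 12658 genes, with 200 genes changed. For the knockout effect under STZ it recovered 41.8% of 67 genes changed by 2-fold and 92.4% of 66 changed by 4-fold, and for the interaction 5.97% and 62.1%. For the STZ effect in floxed controls it recovered 23.9% and 89.4%, for the knockout effect without STZ 26.9% and 81.8%, and for the STZ effect in knockouts 47.8% and 89.4%. Of the genes called in the simulations, 1.32 to 8.64% were false, the highest share being that for the knockout effect without STZ. No unshifted list was called among 39, but the simulated genes varied independently of each other. That setting cannot show how often camera calls a list falsely where its genes vary together. Changes under 2-fold were mostly out of reach of this number of libraries.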

Results

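Muscle gene expression was measured in mice that lack 3 FoxO transcription factors in skeletal muscle and in their floxed littermates, each with and without diabetes induced by streptozotocin (STZ), a toxin of the insulin-producing beta cells. The triple knockout (TKO) was made with a Cre recombinase driven by the skeletal actin promoter ACTA1, which removes floxed parts of Foxo1, Foxo3 and Foxo4 in muscle fibres. FoxO proteins are held outside the nucleus by insulin signalling and turn on genes of protein breakdown and stress resistance when insulin is low. STZ was given at 150 mg/kg after an overnight fast, with 75 mg/kg more on day 3 in females, and animals kept in the study had random blood glucose above 300 mg/dL. The labels give no sex for any library. Xist, the transcript of the inactive X chromosome in females, had 0 counts in 14 of the 21 libraries and at most 2 in the rest, and the Y-linked gene Ddx3y had at least 150 counts in each library.

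The groups held 4 floxed controls, 6 TKO, 5 STZ floxed controls and 6 STZ TKO libraries. Total counts were 4176132 to 7687823 in floxed controls, 2951290 to 6014870 in TKO, 3377613 to 7676700 in STZ floxed controls and 3586183 to 6234979 in STZ TKO libraries. The first principal component held 24.2% of the variance and the second 20.3%. Libraries are named below by their title numbers.

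The targeted genes were examined first. Foxo4 (chromosome X, 101254528 to 101260873, GRCm38) had a mean of 160 ± 29.5 CPM (SD, n = 4) in floxed controls and 6.24 ± 1.52 (n = 6) in TKO muscle, and 190 ± 7.72 (n = 5) and 7.43 ± 2.7 (n = 6) under STZ. Foxo1 (chromosome 3, 52268336 to 52353221) had 68.9 ± 30.6 CPM in floxed controls, 14.6 ± 3.97 in TKO, 56.8 ± 21.1 in STZ floxed controls and 15.8 ± 5.61 in STZ TKO libraries. Every knockout library lay below every floxed library for both genes: the highest knockout values were 12.7 CPM for Foxo4 and 26.7 for Foxo1, and the lowest floxed values 124 and 36.4. Foxo4 fell, with a log2 change of -4.66 ± 0.22 (SE; adjusted p = 3.99e-12) without STZ and -4.67 ± 0.20 (1.84e-12) under STZ in edgeR's quasi-likelihood test. Foxo1 fell too (-2.22 ± 0.30, 0.00028, and -1.84 ± 0.28, 0.000366). Foxo3 (chromosome 10, 42181841 to 42276755) had 73.1 ± 11.3, 96.1 ± 16.6, 90.3 ± 14 and 136 ± 60.7 CPM in the same order of groups, with log2 changes of 0.40 ± 0.25 (0.616) and 0.59 ± 0.23 (0.148) in knockouts. These are counts over the whole gene, which can include exons left in place by the deletion, so the Foxo3 count checks nothing about its knockout.

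**Figure D1:**
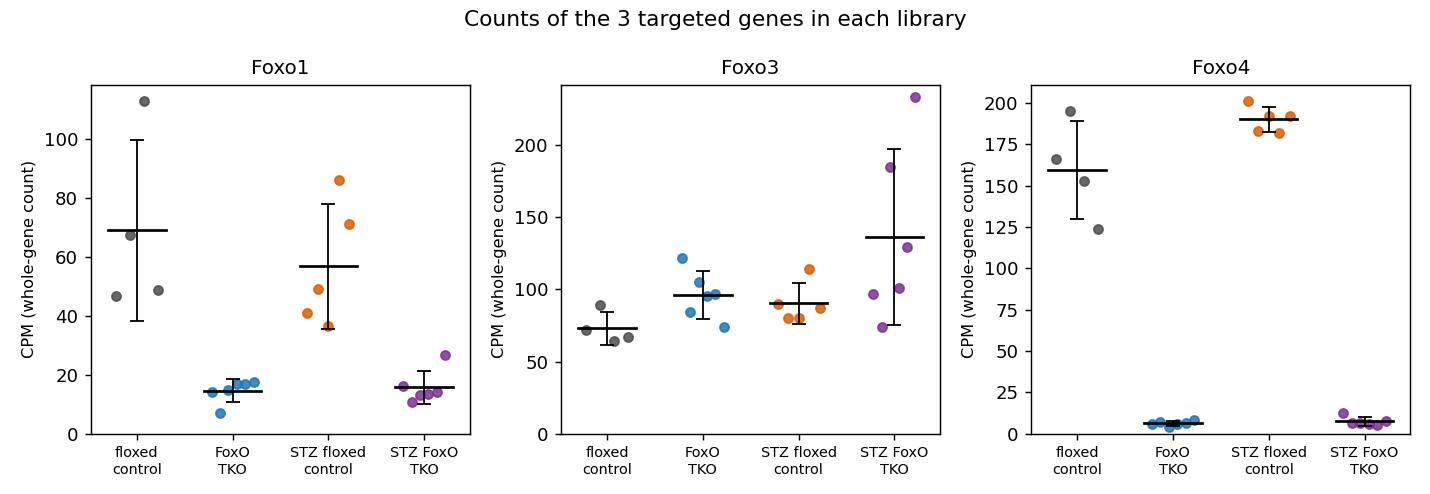
CPM of Foxo1, Foxo3 and Foxo4 in each library, by group; lines are group means and bars the SD. Foxo1 and Foxo4 lie lower in all 12 knockout libraries than in all 9 floxed ones, and Foxo3, counted over the whole gene, does not.

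The first comparison asked how STZ diabetes changed muscle with intact FoxO genes (5 STZ floxed controls against 4 floxed controls). Acot1 and Acot2, thioesterases that release fatty acids from coenzyme A, rose by 4.51 ± 0.51 (adjusted p = 3.9e-05) and 2.64 ± 0.33 (0.000514) on the log2 scale, Acot1 from 0.992 ± 0.564 to 22.5 ± 8.41 CPM. Slc2a4, the insulin-responsive glucose transporter GLUT4, fell (-1.36 ± 0.23, 0.00387), Oxct1, which starts ketone body use, fell (-1.73 ± 0.25, 0.000924), and Scd1, the stearoyl-CoA desaturase of lipid synthesis, fell (-3.06 ± 0.45, 0.00138). Gpx3, a secreted glutathione peroxidase, rose by 1.73 ± 0.30 (0.00678), and the interferon-induced guanylate-binding proteins Gbp5 and Gbp3 rose by 2.57 ± 0.44 (0.00633) and 2.14 ± 0.40 (0.0116). The list of fatty acid oxidation and ketone use had a median of 0.17, with 3 higher, 1 lower and 33 of 37 not past the threshold, or 6 higher and 2 lower adjusted over the list alone (camera 0.00409; adjusted p = 0.691 with an estimated correlation). Acot1 and Acot2 are near-identical neighbours on chromosome 12, so reads may have been divided between them or lost.

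In all, 171 of 12658 genes passed, 63 higher and 108 lower under STZ. Interferon response genes rose as a list, with a median log2 change of 1.02 over 21 genes (camera adjusted p = 3.08e-10; adjusted p = 0.514 with an estimated correlation); 3 rose, none fell and 18 did not pass, or 7 rose when adjusted over the list alone. They were Iigp1 (2.32 ± 0.46), Gbp3 and Gbp2 (1.68 ± 0.37). Of 12 immunoproteasome and antigen presentation genes 1 rose, the peptide transporter Tap1 (1.63 ± 0.39), or 6 adjusted over the list alone (camera 0.000539; adjusted p = 0.514 with an estimated correlation). Cd274, the immune checkpoint ligand PD-L1, and H2-Q7, a class I antigen presentation molecule, rose by 2.55 ± 0.50 and 2.33 ± 0.44.

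Nuclear genes of the respiratory chain lay lower under STZ. All 39 measured genes of complexes II to V had negative fold changes, with a median of -0.84 (camera 2.04e-17; adjusted p = 0.514 with an estimated correlation), of which 3 fell over all genes and 16 adjusted over the list alone. Those were the cytochrome oxidase subunit Cox5b (-1.18 ± 0.26), the ATP synthase subunit Atp5g3 (-1.04 ± 0.23) and cytochrome c1, Cyc1 (-0.85 ± 0.22). All 36 complex I genes were also negative, median -0.77, with 1 past the threshold (Ndufs8, -1.01 ± 0.26) and 4 adjusted over the list alone (camera 8.75e-13; adjusted p = 0.53 with an estimated correlation). Of 21 citric acid cycle genes 1 fell, the pyruvate dehydrogenase subunit Dlat (-0.99 ± 0.20), or 14 adjusted over the list alone (camera 9.61e-11; adjusted p = 0.514 with an estimated correlation). Ppara and Perm1, regulators of oxidative metabolism, fell (-1.40 ± 0.31 and -1.07 ± 0.27). Library 17 had the lowest mean level of complexes II to V among STZ floxed controls, -1.45 against -0.90 to 0.12 in the other 4. The median of complexes II to V was -0.54 with the run as a block and -0.62 without libraries 17 and 18. Ribosomal protein genes, also short and abundant, went the other way, with a median of 0.21 and 0 of 74 past the threshold (camera 0.00451; adjusted p = 0.801 with an estimated correlation).

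Of 30 extracellular matrix genes 5 fell, or 16 adjusted over the list alone, with a median of -0.99 (camera 5.78e-13; adjusted p = 0.514 with an estimated correlation). Among them were the type I collagen chains Col1a1 (-4.43 ± 0.87) and Col1a2 (-3.73 ± 0.71), Sparc (-1.97 ± 0.35) and Col15a1 (-1.95 ± 0.41). Of 10 tendon markers 2 fell, Tnmd (-2.80 ± 0.67) and Cilp2 (-3.45 ± 0.67), or 7 adjusted over the list alone (camera 1.53e-08; adjusted p = 0.395 with an estimated correlation). Fibroblast markers had a median of -0.53 (-0.34 without libraries 17 and 18) with 1 of 13 past the threshold, Col15a1, which is in both lists (camera 0.000616; adjusted p = 0.569 with an estimated correlation). Macrophage markers had a median of 0.14, 0 of 14 past the threshold and a camera adjusted p of 0.78.

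The FoxO-associated growth and stress genes rose as a list, median 0.50 over 20 genes (camera 3.99e-05; adjusted p = 0.395 with an estimated correlation). Catalase (Cat, 1.14 ± 0.22), Sesn1 (1.25 ± 0.25) and Cited2 (0.85 ± 0.20) rose, 17 did not pass, and 5 rose and 1 fell adjusted over the list alone. The muscle ubiquitin ligases Fbxo32 (atrogin-1) and Trim63 (MuRF1) did not pass: Fbxo32 had 625 ± 366 CPM in floxed controls and 2550 ± 1770 under STZ (2.03 ± 0.56, adjusted p = 0.0906), and Trim63 885 ± 435 and 2940 ± 2950 (1.73 ± 0.70, 0.275). Neither did Eif4ebp1, a brake on translation (1.94 ± 0.50, 0.0673), Bnip3 (1.18 ± 0.37, 0.126) or Pdk4 (1.43 ± 0.47, 0.157). Library 17 held the highest Fbxo32, Eif4ebp1, Bnip3 and Cdkn1a counts of its group. Of 18 atrophy ubiquitin ligases none passed, with 1 higher adjusted over the list alone (camera 0.174), and of 32 autophagy genes none (0.221).

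Of the 37 named genes past the threshold, 10 kept their call without any 1 library and in every other setting: Acot1, Acot2, Cacna2d4 (-3.07 ± 0.48), Foxo6os, Gbp3, Gbp5, Gpx3, Oxct1, Scd1 and Slc2a4. The others lost it in at least 1 of these, for example Col1a1 and Cat without library 1 (adjusted p = 0.109 and 0.0743) and Ndufs8 and Perm1 without library 17 (0.147 and 0.134). The count of 171 was 31 without library 1, 50 without 19, 68 without 7, 71 without 17, 73 without 5, 75 without 14, 80 without 9, 92 without 21 and 333 without 3. Foxo6os (-4.96 ± 0.62, adjusted p = 3.9e-05) is antisense to Foxo6 (-2.74 ± 0.59, 0.017; named after its values were seen), and their reads cannot be told apart unless the count used the strand.

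**Figure D2:**
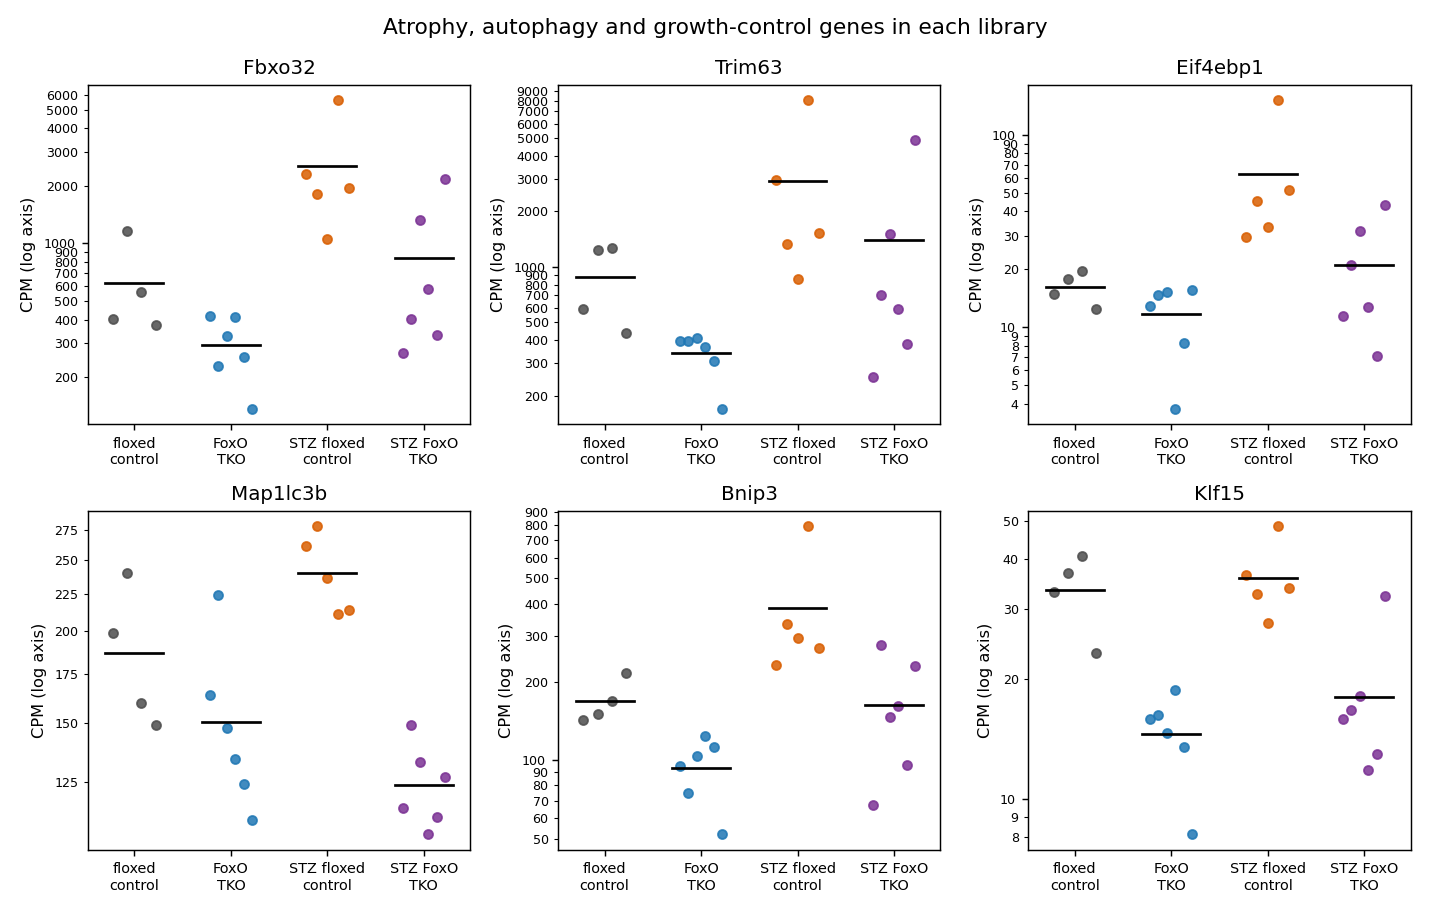
CPM (log axis) of 6 core genes in each library, by group; lines are group means. In STZ floxed controls the highest Fbxo32 (5600 CPM), Bnip3 (795) and Eif4ebp1 (151) values belong to library 17.

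The second comparison asked what the loss of FoxO factors changed in muscle without STZ (6 TKO against 4 floxed controls). Besides Foxo1 and Foxo4, Pik3ip1, an inhibitor of phosphatidylinositol 3-kinase, fell by 2.34 ± 0.22 on the log2 scale (adjusted p = 1.75e-06), from 52 ± 20.5 to 10.3 ± 1.68 CPM. The tetraspanin Tspan8 fell by 3.71 ± 0.44 (0.000107), from 122 ± 32.3 to 9.41 ± 4.1 CPM. Chac1, which breaks down glutathione, fell (-2.77 ± 0.42, 0.00143), as did the potassium channel subunit Kcnab1 (-3.26 ± 0.51, 0.00125), and Pfkfb3, an activator of glycolysis (-2.81 ± 0.50, 0.0074). Klf15, a glucocorticoid-induced transcription factor, fell (-1.22 ± 0.26, 0.0289), as did Odc1, the first enzyme of polyamine synthesis (-1.15 ± 0.26, 0.0358), and Dpysl5 (-2.52 ± 0.57, 0.0372). Ttc9 rose by 1.99 ± 0.34 (0.00623), the sodium channel subunit Scn3b by 1.96 ± 0.36 (0.00963) and the complement protease Masp1 by 2.12 ± 0.43 (0.0243).

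In all, 65 genes passed, 19 higher and 46 lower. The FoxO-associated list fell, with 18 of 20 genes negative and a median of -0.62 (camera 1.24e-12), and this call held with an estimated correlation (adjusted p = 0.0121). Of its genes 2 fell, Pik3ip1 and Klf15, or 10 adjusted over the list alone. Its member Cdkn1a went the other way without passing, with 41 ± 10.4 CPM in floxed controls and 94.8 ± 47.2 in TKO libraries. Atrophy ubiquitin ligases had 17 of 18 genes negative and none past the threshold (median -0.21, camera 0.00383; adjusted p = 0.514 with an estimated correlation), with Fbxo32 at -1.08 ± 0.54 (0.452) and Trim63 at -1.38 ± 0.68 (0.442). Autophagy genes had a median of -0.17 (-0.10 without libraries 4, 15, 16 and 20, -0.05 with the macrophage covariate) with none of 32 past the threshold (camera 0.00275; adjusted p = 0.514 with an estimated correlation). Branched-chain amino acid catabolism genes were negative in 20 of 20, none past the threshold and 6 adjusted over the list alone (median -0.36, camera 7.56e-07; adjusted p = 0.514 with an estimated correlation). Their median was -0.21 without libraries 4, 15, 16 and 20. Fatty acid oxidation genes had a median of -0.33 with none of 37 past the threshold (camera 0.00103; adjusted p = 0.613 with an estimated correlation), and -0.14 with the run as a block. With macrophage marker level as a covariate the medians of the FoxO-associated, branched-chain and fatty acid lists were -0.31, -0.15 and -0.02. The median of the atrophy ligases was -0.07 with this covariate and -0.31 with the run as a block.

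Macrophage markers were higher in TKO muscle, with 14 of 14 positive, a median of 1.77 and a camera adjusted p of 1.72e-12 (adjusted p = 0.514 with an estimated correlation). Over all genes 1 rose, the Fc receptor chain Fcer1g (2.35 ± 0.48, 0.031), and 13 adjusted over the list alone. Mpeg1, a pore-forming protein of macrophages, rose by 4.08 ± 0.79 (0.0394), from 5.53 ± 1.9 to 92.9 ± 101 CPM, and Serpinb1a, a protease inhibitor, by 2.99 ± 0.65 (0.0477). The mean list level was -0.77 ± 0.14 in floxed controls and 0.63 ± 0.87 in TKO libraries, where it ran from -0.41 in library 13 to 2.01 in library 20. Denervation and acetylcholine receptor genes lay higher in the same libraries, with a median of 1.61, none of 21 past the threshold and 10 adjusted over the list alone (camera 9.74e-06; adjusted p = 0.514 with an estimated correlation), and a mean level of 0.34 ± 0.83 against -0.63 ± 0.13. Without libraries 4, 15, 16 and 20 the medians were 1.32 for macrophage markers and 0.74 for denervation genes, and the latter was 0.49 with macrophage marker level as a covariate. Endothelial markers had a median of -0.18, none of 15 past the threshold (camera 0.0145; adjusted p = 0.53 with an estimated correlation).

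Of 16 named genes past the threshold, Foxo1, Foxo4, Pik3ip1 and Tspan8 kept their call without any 1 library and in every other setting. Klf15 lost it without library 9 (adjusted p = 0.13) and Mpeg1, Fcer1g and Odc1 without library 5 (0.142, 0.14 and 0.144), among other libraries. The count of 65 was 32 without library 5, 35 without 9, 40 without 1, 41 without 20, 43 without 16, 102 without 17 and 105 without 13, and 20 with macrophage marker level as a covariate, which differs between the genotypes.

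The third comparison asked what the loss of FoxO factors changed in diabetic muscle (6 STZ TKO against 5 STZ floxed controls). FoxO-associated genes were again lower: Pik3ip1 fell by 2.38 ± 0.21 on the log2 scale (adjusted p = 1.99e-07), as did Cited2 (-1.44 ± 0.18, 4.39e-05), Sesn1, a stress-induced inhibitor of mTOR signalling (-1.66 ± 0.22, 7.1e-05), and Cdkn1b, a cell cycle inhibitor (-0.71 ± 0.17, 0.0125). Map1lc3b, the autophagosome protein LC3B, fell by 0.96 ± 0.18 (0.00212), from 240 ± 29.3 to 123 ± 15.9 CPM. In insulin signalling Akt2 fell (-1.05 ± 0.15, 0.000123), as did Irs1 (-1.64 ± 0.32, 0.00418) and Tsc1 (-1.11 ± 0.23, 0.00551), and Grb14, an adaptor that binds and restrains the insulin receptor, rose by 2.31 ± 0.33 (0.000227), from 6.77 ± 3.28 to 34.1 ± 15.3 CPM. Avil, which encodes the actin-binding protein advillin, fell (-3.18 ± 0.27, 1.85e-07), as did Tspan8 (-3.56 ± 0.41, 3.67e-05), Chac1 (-3.10 ± 0.38, 5.44e-05) and Dpysl5 (-3.34 ± 0.57, 0.000841).

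In all, 619 genes passed, 313 higher and 306 lower. The FoxO-associated list fell with 19 of 20 genes negative and a median of -0.74 (camera 5.78e-13), a call that held with an estimated correlation (adjusted p = 0.0121); 6 genes fell, or 8 adjusted over the list alone. Fbxo32, at 842 ± 750 CPM against 2550 ± 1770, did not pass (-1.60 ± 0.50, 0.0742), nor did Trim63 (-1.08 ± 0.64, 0.39), and none of 18 atrophy ligases did (median -0.17, camera 0.0298; adjusted p = 0.569 with an estimated correlation). Bnip3 fell by 1.24 ± 0.33 (0.0319), but without library 17 its adjusted p was 0.136. Eif4ebp1 fell by 1.55 ± 0.44 (0.046), with 0.214 without library 17. Klf15 fell from 35.8 ± 7.78 to 18 ± 7.43 CPM (adjusted p = 0.0173), a call lost without libraries 4, 15, 16 and 20. Cdkn1a did not pass and had the higher mean in knockouts, 165 ± 125 CPM against 95.9 ± 106. Of 32 autophagy genes 4 fell, or 6 adjusted over the list alone (median -0.20, or -0.13 without libraries 4, 15, 16 and 20 and -0.03 with the macrophage covariate, camera 0.00194; adjusted p = 0.514 with an estimated correlation); the others besides Map1lc3b and Bnip3 were Atg9a (-0.86 ± 0.17) and Wipi2 (-0.54 ± 0.13). Of 24 insulin and IGF signalling genes 2 rose and 6 fell, or 3 and 8 adjusted over the list alone (camera 0.0357; adjusted p = 0.569 with an estimated correlation).

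Odc1 fell (-1.35 ± 0.24), as did Pfkfb3 (-2.59 ± 0.47), the glutamine synthetase Glul (-1.18 ± 0.27) and the proteasome activator Psme4 (-1.11 ± 0.26). Gpx3 and the glutathione transferase Gstm1 fell (-1.32 ± 0.27 and -1.57 ± 0.26). In sterol synthesis the squalene synthase Fdft1 fell (-1.60 ± 0.24), and the list of 18 genes did not pass (camera 0.0642). Acadsb, of branched-chain amino acid breakdown, fell (-1.01 ± 0.20), as did the pyruvate dehydrogenase kinase Pdk2 (-0.82 ± 0.22). Complexes II to V had 37 of 39 genes positive, a median of 0.56 and 1 past the threshold, Atp5l (0.78 ± 0.22), with none adjusted over the list alone (camera 2.37e-05; adjusted p = 0.691 with an estimated correlation). In the citric acid cycle Idh3a (0.83 ± 0.24) and Pdhb (0.69 ± 0.19) rose and Idh2 (-0.99 ± 0.25) fell among 21 genes, with 5 higher and 1 lower adjusted over the list alone (camera 0.00462; adjusted p = 0.691 with an estimated correlation). Complex I genes were positive in 36 of 36, with none past the threshold and a median of 0.43 (camera 0.00232; adjusted p = 0.769 with an estimated correlation). That median was 0.23 with the run as a block and 0.71 without libraries 4, 15, 16 and 20. Atp5l, Idh3a and Pdhb lost their call with the run as a block.

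Of 14 macrophage markers 5 rose, or 12 adjusted over the list alone, with a median of 1.66 (camera 4.23e-07; adjusted p = 0.514 with an estimated correlation), among them lysozyme (Lyz2, 2.59 ± 0.51), Tyrobp (2.32 ± 0.60), Cd14 (2.22 ± 0.57) and C1qc (1.65 ± 0.39). Spp1, the secreted protein osteopontin, rose by 5.79 ± 1.00, from 6.02 ± 4.36 to 324 ± 341 CPM, and the protease Ctsk by 4.52 ± 0.82. Mmp12, a macrophage metalloprotease, had 0.224 ± 0.207 CPM in STZ floxed controls and 39.5 ± 47.1 in STZ TKO libraries, and Itgax, a leukocyte integrin, 0.506 ± 0.358 and 39.5 ± 51.6. Of 30 extracellular matrix genes 4 rose, or 17 adjusted over the list alone (median 1.12, camera 7.17e-08; adjusted p = 0.569 with an estimated correlation): Col3a1 (2.72 ± 0.65), Fn1 (2.15 ± 0.55), Col5a2 (1.91 ± 0.47) and Mmp2 (1.23 ± 0.27). The macrophage level in STZ TKO libraries ran from -0.61 in library 11 to 1.73 in library 4, around a mean of 0.49 ± 1.02 against -0.73 ± 0.24 in STZ floxed controls, and the matrix level from -0.90 to 1.26. Without libraries 4, 6, 15 and 20, which held the 4 highest macrophage levels, Col3a1, Fn1, Col5a2, Mmp2, Mmp9, Itgax, Cd14 and Tyrobp did not pass. Spp1, Ctsk, Mmp12 and Itgax did not pass in limma voom with quality weights, nor with macrophage marker level as a covariate. Without libraries 4, 15, 16 and 20 the medians of the macrophage and matrix lists were 0.84 and 0.38. With macrophage marker level as a covariate the matrix median was 0.05. The macrophage median was then 0.11, which is low by construction, since the covariate is the mean level of the same list.

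Of 60 named genes past the threshold, 38 kept their call without any 1 library and 18 also in every other setting, among them Akt2, Avil, Cited2, Grb14, Irs1, Map1lc3b, Pik3ip1, Sesn1 and Tspan8. Col3a1 and Fn1 lost it without library 4 (adjusted p = 0.0755 and 0.108) and Mmp9 (4.76 ± 1.18) without library 18 (0.101), among other libraries. The count of 619 was 380 without library 21 and 407 without 7, 267 with macrophage marker level as a covariate, 312 with only both compared groups in the fit and 1068 with the run as a block.

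**Figure D3:**
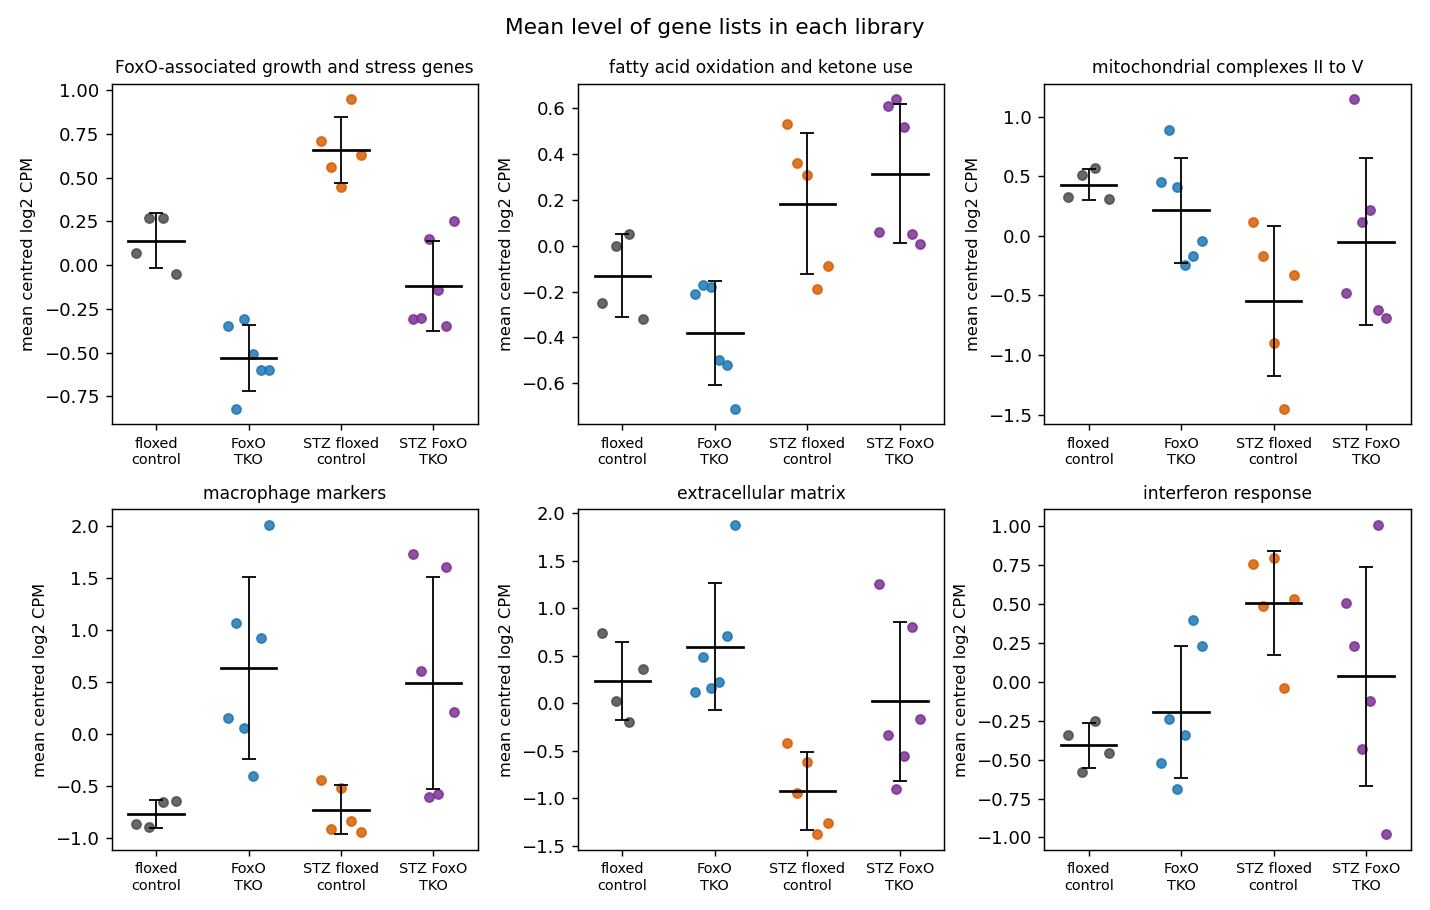
Mean centred log2 CPM of 6 gene lists in each library, by group; lines are group means and bars the SD. FoxO-associated genes lie at -0.82 to -0.31 in TKO and 0.45 to 0.95 in STZ floxed control libraries, while macrophage markers range from -0.61 to 1.73 within STZ TKO libraries.

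The fourth comparison asked how STZ changed muscle without FoxO factors (6 STZ TKO against 6 TKO). Genes of fatty acid use rose: Acot1 by 4.18 ± 0.44 on the log2 scale (adjusted p = 1.28e-05), Acot2 by 2.53 ± 0.29 (0.000177), the lipid droplet protein Plin5 by 1.79 ± 0.27 (0.00413) and the fatty acid transporter Cd36 by 1.42 ± 0.23 (0.00676), from 329 ± 108 to 879 ± 259 CPM. Oxct1 fell (-1.14 ± 0.22, 0.0295), as did Scd1 (-2.06 ± 0.38, 0.0312) and Foxo6os (-2.68 ± 0.38, 0.0027). Catalase (1.00 ± 0.19, 0.0253), Rab15 (1.71 ± 0.32, 0.0253) and Kcnf1 (2.87 ± 0.57, 0.0426) rose, and the transporter Slc47a1 fell (-0.91 ± 0.19, 0.0486).

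In all, 18 genes passed, 12 higher and 6 lower. The list of fatty acid oxidation and ketone use had 34 of 37 genes positive and a median of 0.59 (camera 9.4e-22; adjusted p = 0.172 with an estimated correlation), with 5 higher, 1 lower (Oxct1) and 31 not past the threshold, or 19 higher and 1 lower adjusted over the list alone. FoxO-associated genes had a median of 0.44, with Cat past the threshold and 2 higher adjusted over the list alone (camera 0.00017; adjusted p = 0.395 with an estimated correlation), and a median of 0.24 without libraries 17 and 18. Fbxo32 (1.51 ± 0.48, 0.28), Trim63 (2.03 ± 0.61, 0.256) and Pdk4 (1.67 ± 0.41, 0.112) did not pass, and atrophy ligases had a median of 0.24 with none of 18 past the threshold (camera 0.035; adjusted p = 0.569 with an estimated correlation). Extracellular matrix genes had a median of -0.55 with none of 30 past the threshold (camera 8.18e-07; adjusted p = 0.569 with an estimated correlation). Complex I and complexes II to V had medians of -0.16 and -0.19 (-0.34 and -0.31 with the run as a block, -0.01 and -0.03 without libraries 17 and 18) with none past the threshold (camera 0.007 and 0.0103; adjusted p = 0.798 and 0.801 with an estimated correlation).

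Acot1, Acot2, Foxo6os and Plin5 kept their call without any 1 library and in every other setting. Scd1 and Oxct1 lost it without library 11 (adjusted p = 0.108 for both), among other libraries. The count of 18 was 7 without library 2, 11 or 13, 8 without 6 or 12, 9 without 16, 11 without 10 or 18, 34 without 8, 51 without 17 and 61 without 4, and 98 with the run as a block.

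The interaction tested whether the response to STZ differed between the genotypes. Ddah1 (chromosome 3, 145758675 to 145894277), which breaks down inhibitors of nitric oxide synthase, was past the threshold, with a difference of 1.92 ± 0.30 on the log2 scale (adjusted p = 0.0179). It had 10.6 ± 1.97 CPM in floxed controls and 2.63 ± 0.719 under STZ, against 22.2 ± 2.97 and 21.7 ± 5.85 in TKO and STZ TKO libraries. No other gene passed, with 493 genes at an unadjusted p under 0.05 in edgeR, 4 past the threshold in DESeq2 and 2 in limma voom. The 493 are fewer than the share of 0.05 of 12658 tested genes that chance alone would give. The difference for the core genes had an adjusted p of 1 throughout, with Fbxo32 at -0.52 ± 0.74, Trim63 at 0.30 ± 0.93, Map1lc3b at -0.65 ± 0.26, Eif4ebp1 at -1.07 ± 0.67 and Slc2a4 at 0.59 ± 0.30. So passing under STZ in 1 genotype alone was not shown to be a difference for these genes. The Ddah1 call was lost without library 5 (adjusted p = 0.0866), 19 (0.0815), 21 (0.0654), 7 (0.0586), 17 (0.0523) or 10 (0.0501), and with the run as a block (0.191).

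Among lists the STZ effect on complexes II to V was less negative in knockouts, with 39 of 39 differences positive and a median of 0.66 (camera 3.71e-13; adjusted p = 0.514 with an estimated correlation). Interferon response genes had a median difference of -0.76 with 20 of 21 negative (camera 1.94e-08; adjusted p = 0.514 with an estimated correlation), and fatty acid oxidation genes 0.44 with 30 of 37 positive (camera 9.76e-07; adjusted p = 0.514 with an estimated correlation). With the run as a block the median differences were 0.31 for complexes II to V and 0.11 for fatty acid oxidation. No member of these lists passed over all genes, and 1 of complexes II to V passed adjusted over the list alone. Fry called 0 of 40 lists for the interaction, in a direction or as mixed. FoxO-associated genes had a median difference of -0.13 (camera 0.201), and atrophy ligases 0.12 (0.836).

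Over 12648 genes the slope of the STZ effect in knockouts on that in floxed controls was 0.764 (jackknife SE 0.475), where 1 means equal size. Of 100 labellings of the genotype, the real one included, 52 gave a slope as low, a one-sided permutation p of 0.52 (two-sided 0.98). The permuted slopes had a median of 0.722 and ran from -0.112 to 47.8, so a slope under 1 does not by itself mean a smaller response. The slope gave no difference beyond the spread between libraries. Across genes, which are not independent replicates, both STZ effects correlated with r = 0.529; they share no library. Of the 171 genes past the threshold in floxed controls 159 had the same sign in knockouts, with a median ratio of 0.369, a ratio that selection on the floxed controls lowers. Of these, 5 rose and 4 fell in both genotypes, where independent lists would share 0.06 and 0.051.

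Both knockout effects, which share no library either, correlated with r = 0.683 across genes. Of the 65 genes past the threshold without STZ 64 had the same sign under STZ, with a median ratio of 0.963, and 15 rose and 43 fell in both, where independent lists would share 0.47 and 1.1.

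**Figure D4:**
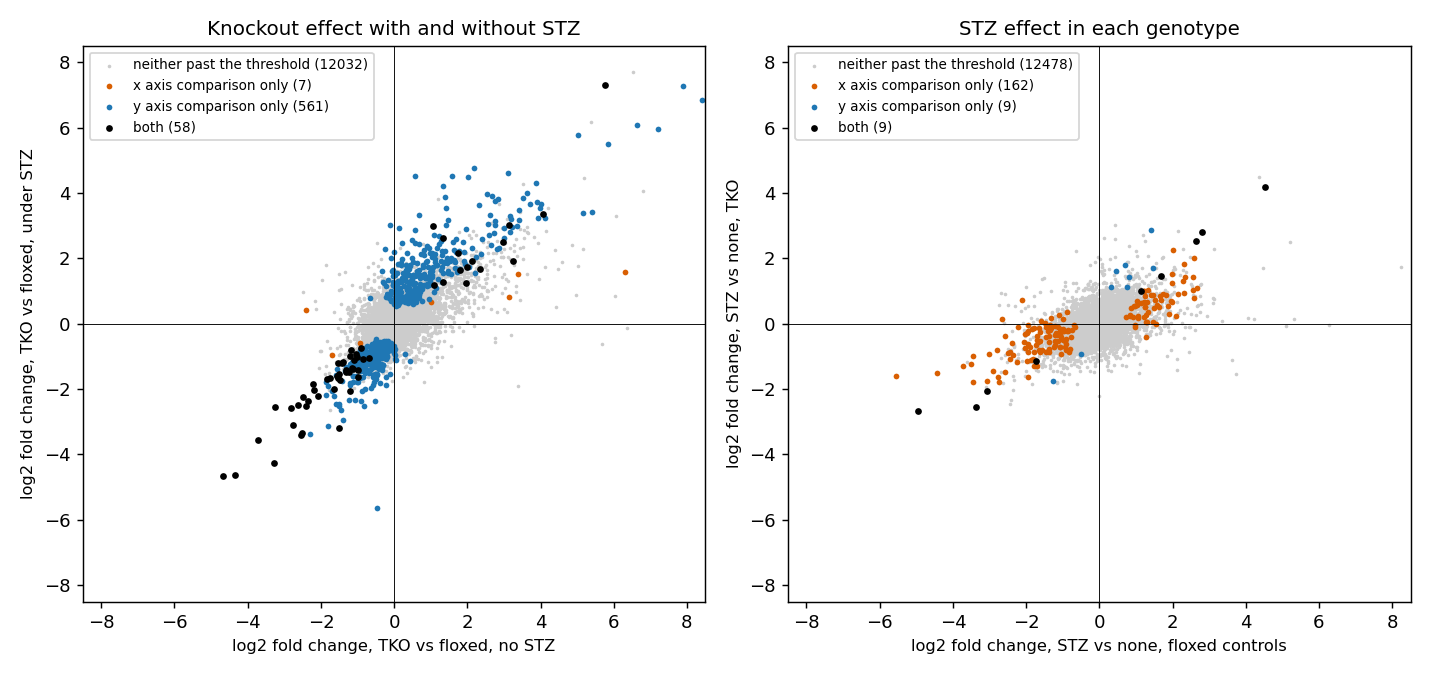
Log2 fold changes of all tested genes for the knockout effect without (x) and with STZ (y), left, and for the STZ effect in floxed controls (x) and knockouts (y), right; colours mark genes past the threshold in the comparisons named. Of the genes past the threshold in both, 58 changed the same way in both knockout effects and 9 in both STZ effects.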

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

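The tests in this part were chosen after the results were seen, except the interaction tests of the report and the test of the library runs. Libraries 17 and 18 were picked for leaving out because they were seen to stand apart, and only the bounds of those tests were written before their results.

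In 20 of 228 sets of values per group, 1 library lay apart from the others of its group by Dixon's criterion, where chance alone sets about 1 in 20 apart. STZ floxed control library 17 stood apart 6 times, with the highest Fbxo32 (5600 CPM against 1060 to 2310 in the others), Bnip3 (795 against 232 to 333), Eif4ebp1 (151 against 29.5 to 52), Cdkn1a (283 against 32.9 to 69.5) and ribosome biogenesis level (0.76 against -0.08 to 0.01) and the lowest smooth muscle level (-0.26 against 0.19 to 0.27). TKO library 20 also stood apart 6 times, with the highest levels of extracellular matrix (1.88 against 0.12 to 0.71), tendon markers (1.16 against 0.24 to 0.55) and satellite cell markers (1.15 against -0.11 to 0.25) and the lowest of glycolysis (-0.53 against 0.12 to 0.33), branched-chain amino acid catabolism (-0.53 against -0.01 to 0.19) and autophagy (-0.43 against -0.14 to -0.05). STZ TKO library 18 had the highest Trim63 (4920 CPM against 253 to 1510), Klf15 (32.4 against 11.8 to 18.1) and Foxo1 (26.7 against 10.9 to 16.1) of its group. STZ TKO library 8 had the lowest total count (3586183 or 3.59 mega-counts, against 5.3 to 6.23) and the lowest levels of lipid synthesis (-0.52 against -0.03 to 0.04) and endothelial markers (-0.54 against -0.10 to 0). Foxo1 was lowest in TKO library 6 (7 CPM against 14.1 to 17.7) and Foxo4 highest among STZ TKO libraries in library 4 (12.7 against 5.35 to 7.77).

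The response to STZ differed between the genotypes for Ddah1 (difference 1.92 on the log2 scale), a call lost without library 5 (adjusted p = 0.0866), 7 (0.0586), 10 (0.0501), 17 (0.0523), 19 (0.0815) or 21 (0.0654) in edgeR. The Ddah1 call was also lost with the run as a block and without libraries 4, 15, 16 and 20 or 4, 6, 15 and 20. Camera also called 18 gene lists for the interaction, none of which passed with an estimated correlation, and fry called 0 of 40, in a direction or as mixed. A positive difference means a higher STZ effect in knockouts than in floxed controls, not a higher level. The difference was positive for complexes II to V (camera adjusted p = 3.71e-13), the citric acid cycle (3.44e-09) and complex I (2.22e-08). It was also positive for fatty acid oxidation (9.76e-07), mitochondrially encoded genes (3.11e-06), tendon markers (8.17e-05), extracellular matrix (0.000143), glycolysis (0.00107) and mitochondrial biogenesis (0.0118). The same held for fast fibre genes (0.0118), glucocorticoid response (0.0464) and slow fibre genes (0.0464). With the run as a block the median difference was 0.31 instead of 0.66 for complexes II to V, 0.17 instead of 0.58 for complex I, 0.11 instead of 0.44 for fatty acid oxidation and 0.06 instead of 0.39 for fast fibre genes. The difference was negative for interferon response (1.94e-08), immunoproteasome genes (0.000569), Schwann cell markers (0.0044), ribosome biogenesis (0.00451) and satellite cell markers (0.0304). It was also negative for ribosomal proteins (0.0079), but in the opposite direction without libraries 4, 6, 15 and 20 (0.000483).

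Macrophage markers lay higher in knockouts, Lyz2 among the most abundant with 108 ± 29.4 CPM in STZ floxed controls and 653 ± 560 in STZ TKO libraries. A lower share of muscle fibres would raise the markers of another cell type only if that type did not become rarer too, so single lists cannot decide it. Without STZ the endothelial list lay lower (median -0.18 ± 0.05 over 15 genes, -0.11 without libraries 4, 15, 16 and 20). Extracellular matrix genes had a median of 0.39 that turned to -0.06 without these libraries and -0.67 with the macrophage covariate, library 20 standing apart as the highest. A lower fibre share stays open. The library runs left a difference of 1.40 ± 0.49 in the mean list level without STZ when fitted as a block, which argues against them as the whole cause. Fibre regeneration that differs between knockout animals may go with more macrophages: their level correlated with that of denervation genes over 12 knockout libraries (r = 0.592, permutation p = 0.0384), but not past the threshold by rank (rho = 0.427, p = 0.165) or without libraries 20 and 4 (r = 0.142, p = 0.69). Satellite cell markers decide nothing (median 0.44 without STZ, where library 20 stood apart, and 0.11 under STZ, camera 0.535), so this stays open, as does a change in macrophages themselves, which was not tested.

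Nuclear respiratory chain genes lay lower under STZ in floxed controls, as did mitochondrially encoded genes (median -0.55, 11 of 12 negative, camera 0.00232; 0.569 with an estimated correlation) and glycolysis and glycogen genes (-0.50, 26 of 32 negative, 2.2e-05; 0.514), so the difference was not particular to them. Loss of short transcripts would lower ribosomal protein genes too, and these had a median of 0.21 ± 0.04 over 74 genes. Errors of list medians in this part are SE over genes, not over libraries. The ribosomal level was -0.10 ± 0.23 (SD, n = 4) in floxed controls and 0.08 ± 0.44 (n = 5) under STZ. A rise was therefore not established. The level of complexes II to V went from 0.43 ± 0.13 to -0.54 ± 0.63. Without such a fall in ribosomal genes, loss of short transcripts is argued against only as the whole cause. Without libraries 17 and 18 the median of complexes II to V was -0.62 ± 0.06 over 39 genes, against -0.84 with them and -0.54 with the run as a block, so part of the size may rest on library 17 or on the runs, and the bound of 3 parts in 4 set beforehand was not reached. Slow fibre genes, which less slow muscle in the sample would lower, had a median of 0.02 ± 0.12 over 16 genes, between the bounds set for this test. Their level was -0.12 ± 0.32 (SD, n = 4) in floxed controls and -0.15 ± 0.2 (n = 5) under STZ. Fast fibre genes, which less slow muscle would not lower, had a median of -0.63, or -0.36 with the run as a block. These values argue against less slow muscle as the whole cause. Libraries 17 and 18 and the runs stay open beside an effect of diabetes, as do less slow muscle and loss of short transcripts as parts of the cause.

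Of genes past both thresholds, 29 rose under STZ in floxed controls and were lower in knockouts under STZ, and 39 did the opposite, where independent lists would share 1.5 and 2.7. Both comparisons share the STZ floxed controls, whose noise alone gives opposite signs: simulations without an effect gave 0 such genes and a covariance of -0.0641, against -0.122 observed, while the correlation across genes was weaker than in the simulations (-0.326 against -0.49). With these controls split between the comparisons the covariance had a median of -0.0616 over 20 splits (-0.133 to 0.0626) and the counts medians of 3.5 and 4, so an effect and the noise of shared libraries cannot be told apart here, with too few libraries per part. The count of 68 was 17 without library 1, 22 without 19, 29 without 17, 31 without 7 or 9, 34 without 21, 35 without 5, 38 without 14 and 125 without 3. Without libraries 17 and 18 together, 40 of the 68 still passed both, a number between the bounds set beforehand, so how far those libraries account for the count stays open.

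Other splits of the same libraries into groups of the same sizes were counted for each comparison, 100 splits with the real one, drawn without holding the library runs. The share of splits as large was under 0.05 for the STZ effect in floxed controls (171 genes, 2 of 100, highest other 208). It was also under 0.05 for the knockout effect without STZ (65, 1 of 100, highest other 24) and under STZ (619, 1 of 100, highest other 409). These shares make chance alone unlikely but do not exclude it. Splits that do not hold the runs cannot exclude an effect of the runs. For the interaction (1 gene; 3 of 100, highest other 85) the share was also under 0.05, but the count was 0 with the run as a block and without library 5, 7, 10, 17, 19 or 21, so little rests on it. With the run as a block the first 3 comparisons had 245, 92 and 1068 genes, and the 171 were 31 without library 1. The split with 208 genes differs from the real one only in setting STZ floxed control library 3 among the untreated. Chance cannot be excluded for the STZ effect in knockouts (18 genes; 6 of 100, highest other 712). All 5 other splits as large put libraries 4, 15, 16 and 20 on the same side and called 167 to 712 genes, which points to a structure of the knockout libraries other than STZ.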

How the results depend on the processing

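The alternatives without libraries 17 and 18, without libraries 4, 15, 16 and 20 or 4, 6, 15 and 20, with a macrophage covariate, and with the run block without libraries 17 and 18 were chosen after the data were seen.

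Of 126 calls of named genes none reversed. DESeq2 kept 126, RLE factors 123, the run block 115, voom 107, the run block without libraries 17 and 18 102, leaving out 17 and 18 99, leaving out 4, 6, 15 and 20 97 of 125, leaving out 4, 15, 16 and 20 94 of 125, no filter 92, the fit of only the compared groups 89 of 124 and the macrophage covariate 80. Leaving out each library in turn kept 61 throughout. RLE factors kept all 5 counts within 1.5 times (171, 65, 633, 24 and 1).

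The STZ effect in floxed controls (171 genes) gave 421 in DESeq2, 770 in voom, 265 with only the compared groups, 293 with the macrophage covariate and 283 without 4, 6, 15 and 20, and 31 to 333 without each library in turn. The knockout effect without STZ (65) gave 346 in DESeq2, 256 in voom, 125 without 17 and 18, 159 with the run block as well, 40 without 4, 15, 16 and 20, 37 without 4, 6, 15 and 20 and 20 with the macrophage covariate, and 32 to 105 without each library. The knockout effect under STZ (619) gave 985 in DESeq2, 312 with only the compared groups, 1068 with the run block and 267 with the macrophage covariate, and 380 to 780 without each library. The STZ effect in knockouts (18) gave 112 in DESeq2, 53 in voom, 29 without a filter, 4 with only the compared groups, 98 with the run block, 28 without 17 and 18, 41 with the run block as well, 32 without 4, 6, 15 and 20 and 29 with the macrophage covariate, and 7 to 61 without each library. The interaction (1 gene) gave 4 in DESeq2, 2 in voom, 2 without a filter and 0 with the run block, with or without 17 and 18, without 4, 15, 16 and 20 and without 4, 6, 15 and 20, and 0 to 2 without each library. Fewer libraries enter the fits that leave some out; otherwise the cause was not tested.

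Of 87 list calls by camera 2 held with an estimated correlation, both of FoxO-associated genes, and fry called 7 in a direction and 33 as mixed; fry asks whether a list changed at all, not whether it changed more than other genes. Leaving out each library gave 76 to 94 calls, and slopes of 0.584 to 1.06. Leaving out 17 and 18 kept 74 list calls, the run block 69, leaving out 4, 6, 15 and 20 68, the macrophage covariate 58, the run block without 17 and 18 55 and leaving out 4, 15, 16 and 20 53.

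Reversed in sign, with camera adjusted p for lists, were: without 17 and 18, Klf15 under STZ in floxed controls (-0.03, and -0.02 in voom); with the run block, Trim63 in the interaction (-0.19; -0.01 with the macrophage covariate; -0.78 with the run block without 17 and 18); with the run block without 17 and 18, Ctsl in knockouts under STZ (0.08), immediate early genes under STZ in floxed controls (0.939) and, in the interaction, glucocorticoid response (0.952) and fast fibre genes (0.604); with the macrophage covariate, in knockouts without STZ, immunoproteasome (0.609), lysosome (0.761), citric acid cycle (0.643) and extracellular matrix (6.79e-12); without 4, 6, 15 and 20, complex I (0.416) and complexes II to V (0.419) in the STZ effect in knockouts and ribosomal proteins in the interaction (0.000483). Without each library in turn, Foxo1 ranged from -0.45 to 0.07, Gabarapl1 from -0.09 to 0.44 and Klf15 from -0.05 to 0.20 under STZ in floxed controls, and Trim63 from -0.72 to 1.08 in the interaction. The cause was not tested. The macrophage covariate differs between genotypes, so it removes part of the knockout effect by construction.

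The planned sex covariate, alone and with the run block, was not run, since Xist counts gave no library the female pattern. The number and depth of the libraries left a median standard error of 0.252 to 0.385 on the log2 scale, the largest for the interaction.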

Other observations

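The opposed genes Mb, Map2k6, Ckmt2, Tfrc and Mpp3 below were named after their values were seen, and this part reports no other test chosen then.

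Under STZ in floxed controls fast fibre genes lay lower (median -0.63, or -0.36 with the run as a block; none of 16 past the threshold and 3 adjusted over the list alone; camera 0.000127; adjusted p = 0.569 with an estimated correlation), while slow fibre genes had a median of 0.02. In knockouts under STZ the calcium store protein Casq1 rose by 1.31 ± 0.33 on the log2 scale (adjusted p = 0.0236; 0.0539 without library 14). Clock genes lay higher under STZ in knockouts (median 0.38, or 0.22 with the run as a block; 16 of 18 positive; camera 0.00284; adjusted p = 0.569 with an estimated correlation), and in knockouts under STZ the clock repressor Bhlhe41 rose by 1.04 ± 0.26 (0.0216; 0.0531 without library 17). Of 21 glucocorticoid response genes, which include Foxo1, 2 fell in knockouts without STZ (Foxo1 and Klf15; camera 0.00034; adjusted p = 0.514 with an estimated correlation), and 4 in knockouts under STZ, with Glul and Cebpd (-1.34 ± 0.37; adjusted p 0.107 without library 17) as the others, where the list had a median of 0.02 with 11 positive and 10 negative (camera 0.225). Dok7, which organizes the neuromuscular junction, rose in knockouts under STZ by 0.98 ± 0.23 (0.0129).

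Adipocyte markers had medians of -0.63 (-0.38 with the run as a block) and -0.79 in knockouts without and with STZ and none of 12 past the threshold (camera 0.0228 and 0.00981; adjusted p = 0.691 and 0.613 with an estimated correlation). In knockouts under STZ 1 of 12 smooth muscle markers fell, Myh11 (-0.90 ± 0.22; adjusted p 0.0631 without library 7). The proteasome, heat shock, amino acid stress, blood cell, sterol and antioxidant lists passed camera in no comparison, although Chac1, Fdft1, Gpx3, Gstm1, Herpud1 and Psme4 in them passed singly in knockouts under STZ. Of 4 measured lymphocyte markers none passed in any comparison, nor did any of 4 measured Y-linked genes, whose lowest values over the libraries were 55.3 CPM for Ddx3y, 45.7 for Eif2s3y, 10.7 for Kdm5d and 3.32 for Uty.

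Among genes past both thresholds with opposite signs were myoglobin (Mb, -2.65 under STZ in floxed controls and 2.92 in knockouts under STZ), the kinase Map2k6 (-2.21 and 2.03), the mitochondrial creatine kinase Ckmt2 (-1.66 and 1.35), the transferrin receptor Tfrc (-1.83 and 1.84) and the scaffold Mpp3 (-2.04 and 2.63). Their interaction had adjusted p of 0.48, 0.141, 1, 0.925 and 0.502 in edgeR, so none was shown to respond to STZ differently by genotype.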
